A study of Mus musculus with 6 samples.

How the data were processed

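RNA was measured in cells from mouse gliomas that the labels name tumor-associated endothelial cells. Per the labels, they were taken from the tumors by magnetic sorting with an antibody against CD105 (endoglin, the product of Eng) and then kept for 12 h in medium conditioned by glioma cells. The 6 arrays came from 6 mice, with 1 array per mouse. Cells of 3 mice carried Tie2-Cre together with 2 floxed Pfn1 alleles (fl/fl) and the Y129F form of Pfn1 (mice 1, 3 and 4, the Tie2-Cre group). Cells of the other 3 mice carried the same Pfn1 alleles without Cre (mice 6, 7 and 10, the no Cre group). How Cre rearranges these alleles is not given in the sources used here.

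Total RNA was extracted with TRIzol, labelled with biotin and hybridized to Affymetrix Mouse Gene 2.0 ST arrays, per the labels and the series text. The deposited values were made by the authors with RMA in Affymetrix Expression Console, per the labels and the submitters' processing notes. The version of that program is not given in the sources used here. The deposited values are intensities on a linear scale, from 5.13 to 17822, and their log2 was taken before any test. RMA includes background correction and quantile normalization, and no further scaling was applied. No detection call came with the values, so the change of a gene that was dim in 1 group is understated by the background. No genome build was named and no coordinate is given.

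The table held 41345 probe sets. Of these, 23521 had exactly 1 gene symbol in the array annotation, 1814 had several and 16010 were not listed. Identifiers of 23328 of the single-symbol probe sets were found in a mouse RefSeq gene table and those of 193 were not, and 0 symbols were updated. Where several probe sets carried 1 symbol, the one with the highest mean over all 6 arrays was used, which set 1341 aside and left 22180 genes. Control probe sets could not be told from other unlisted ones and entered no test of genes. The number of arrays limits the precision: the median SD over genes was 0.10 log2 in the Tie2-Cre group and 0.089 in the no Cre group.

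The Tie2-Cre group was compared with the no Cre group by limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, two-sided), with version 1.17.8 of data.table for reading. The Benjamini-Hochberg adjusted p had to lie under 0.05. Changes are log2 differences, Tie2-Cre minus no Cre, with the standard error (SE) of the limma fit. Mouse numbers differ between the groups, so no mice were paired. The level of Pfn1 was also compared by an exact permutation test, two-sided, for which 3 mice against 3 cannot give a p below 0.1. A list of genes was tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists tested. Camera with an estimated correlation and fry were alternatives.

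The groups, the tests, the alternatives, the rule for named genes and 28 gene lists were fixed before the data were examined. The lists were hypoxia response, glycolysis, HIF pathway components, angiocrine factors, angiogenesis and tip cell genes, endothelial identity, blood-brain barrier, profilin and actin regulators, SRF and YAP targets, adhesion and inflammation, interferon response, cell cycle, basement membrane and matrix, unfolded protein response, immediate early genes, oxidative phosphorylation, cholesterol synthesis, p53 targets, and markers of microglia and macrophages, T and NK cells, neutrophils and monocytes, pericytes and smooth muscle, fibroblasts, astrocytes with progenitors and glioma, neurons, oligodendrocytes and red blood cells, with sex-linked genes as the last. The 26 lists with at least 5 measured genes were tested. The red blood cell markers, with 3 measured, and the sex-linked genes, with 4, were only described. Members that were not among the 22180 genes were not analysed here.

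Pfn1 was always named. Beyond it, the rule named the 15 largest rises and the 15 largest falls on the log2 scale among genes past the threshold whose 3 arrays of 1 group all lay beyond the 3 of the other. It also named up to 4 members of each list with the smallest p in either direction. Pseudogenes, Gm-numbered, Rik and small RNA symbols were counted and not named, which skipped 0 among the rises and 1 among the falls. The rule took 130 genes, and genes beyond it are said to have been named after their values were seen.

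Alternatives were the addition of the 17824 probe sets without a single symbol, a minimum mean log2 of 5, leaving out the dimmest 33.3% of genes, quantile normalization of the deposited values again, centring each array on its median, the mean of the probe sets of a gene, eBayes with trend and robust, array weights, the mean of the macrophage list per array as a covariate, an unadjusted p under 0.05 with a change of at least 1.5-fold, and leaving out each mouse in turn. The pipeline was tested on simulated data of the same size. It recovered 40 of 67 genes (59.7%) shifted by 0.5 log2, 67 of 67 shifted by 1 and 66 of 66 shifted by 2, and 5 of its 178 calls (2.81%) were false. A simulated list shifted by -0.35 was called by camera, by camera with an estimated correlation (adjusted p 0.00155) and by fry (adjusted p 0.000192). Camera called 0 of 23 unshifted lists. The simulated genes varied independently of each other, so this does not show how often camera calls lists of genes that vary together. In the real data, the estimated correlation was 0.60 for the glycolysis list. Levels of lists were set against 10000 random lists of the same size (seed 1). Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3.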

Results

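Expression of 22180 genes was measured in cells of 6 mice that had been sorted from gliomas for CD105 and are labelled as tumor-associated endothelial cells, 3 with Tie2-Cre and 3 without Cre, all with both Pfn1 alleles floxed (fl/fl) and the Y129F form. The series asks how phosphorylation of profilin-1, an actin-binding protein, bears on gene expression in these cells. The median log2 intensity per array lay between 6.64 and 6.69. Pearson's r across genes was 0.994 to 0.996 between arrays of a group and 0.986 to 0.988 between arrays of different groups. The first principal component held 62.0% of the variance and parted the groups, with the Tie2-Cre arrays at 20.4 to 22.7 and the no Cre arrays at -22.2 to -21.5.

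The median log2 level over all 6 arrays was 7.06 for the endothelial identity list, at the 43.8th percentile of random lists of its size, 10.69 for fibroblast markers, above all random lists, and 8.48 for pericyte and smooth muscle markers, at percentile 98.2. Mean levels were 6.23 for Pecam1, 6.89 for Cdh5, 5.79 for Tek (the gene of Tie2), 5.91 for Cldn5 and 4.27 for Emcn, and 11.91 for Eng, the sorting antigen, all named after their values were seen. Probe sets differ in brightness, so these levels give neither cell shares nor the identity of the cells.

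Pfn1 itself showed a like signal in both groups. Its log2 intensity was 12.41 ± 0.0045 (SD, n = 3 mice) with Tie2-Cre and 12.37 ± 0.026 (SD, n = 3 mice) without Cre. The change of 0.04 (SE 0.062) did not pass the threshold (limma adjusted p 0.776), and its 95% confidence interval ran from -0.10 to 0.18. The exact permutation test gave p = 0.1, the smallest that 3 mice against 3 allow. The probe set does not tell the Y129F form from the unchanged gene.

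Cells with Tie2-Cre differed from cells without Cre in 2652 of the 22180 genes (12.0%), with 1061 higher and 1591 lower. Outside the sex-linked genes, the largest rises included the matrix gene Dpt and the chemokine genes Ccl5 and Ccl3, and the largest falls the inducible nitric oxide synthase Nos2 and the ecto-nucleotidase Nt5e. At least 2-fold changes were seen in 134 of the higher and 171 of the lower genes. The median absolute change of the genes past the threshold was 0.47 log2, and the groups of 3 arrays did not overlap in any of them. Over all genes, the groups did not overlap in 6885 (31.0%, against 10% by chance), and the median change was -0.0042. The 2 counts depended on the mice: leaving out no Cre mouse 6, 7 or 10 gave 667, 676 or 634 higher genes, and leaving out Tie2-Cre mouse 1 or no Cre mouse 6, 7 or 10 gave 1046, 1022, 910 or 1026 lower genes. With the macrophage list as a covariate, which itself parted the groups, 82 genes were higher and 152 lower, and with an unadjusted p under 0.05 and a change of at least 1.5-fold the counts were 424 and 551.

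Among the largest rises were the matrix protein dermatopontin (Dpt, log2 change 3.54, SE 0.10, adjusted p 1.89e-06), the proteolipid-family membrane glycoprotein Gpm6b (3.28, SE 0.12), and the stromal gene Islr (2.94, SE 0.080). The chemokines Ccl5 and Ccl3 rose by 2.94 (SE 0.22) and 2.92 (SE 0.27). The water channel Aqp1 rose by 2.63 (SE 0.099), the matrix protein periostin (Postn) by 2.36 (SE 0.14), the sphingosine-1-phosphate receptor S1pr3 by 2.34 (SE 0.24) and the sodium pump subunit Atp1b1 by 2.25 (SE 0.12). C1qtnf7 (2.23, SE 0.15), the integrin subunit Itga8 (2.20, SE 0.23) and the transcription factor Dach1 (2.18, SE 0.15) completed the rises outside the sex-linked genes. Of the falls, Pkhd1l1 changed by -3.86 (SE 0.11, adjusted p 1.89e-06), the hydroxysteroid dehydrogenase Akr1c18 by -3.48 (SE 0.13), the uroplakin Upk1b by -3.29 (SE 0.16) and the small proline-rich protein Sprr2e by -3.20 (SE 0.11). Nos2 changed by -3.06 (SE 0.22, adjusted p 0.000144), from a mean of 10.57 without Cre to 7.52 with Tie2-Cre. Lower were also Serpinb2, a plasminogen activator inhibitor (-2.87, SE 0.18), the glutathione transferase Gstk1 (-2.81, SE 0.13), the prostaglandin dehydrogenase Hpgd (-2.80, SE 0.14) and Tnfsf18, the ligand of the receptor GITR (-2.75, SE 0.16). Nt5e (-2.66, SE 0.099), the membrane glycoprotein Gpm6a (-2.64, SE 0.075), the carboxypeptidase Folh1 (-2.64, SE 0.11) and the tetraspanin Cd53 (-2.34, SE 0.11) followed. The hepcidin gene Hamp was lower by 3.15 (SE 0.15) and lay at 3.65 with Tie2-Cre, so that the background limits its fold. With the macrophage covariate, the calls of S1pr3 (2.73, SE 0.46) and Itga8 (1.74, SE 0.43) were lost, and with them 97 of the calls of all 147 named genes that had passed the threshold. Over these 97, the median ratio of the change with the covariate to that without was 1.01 and that of the SE was 2.00. Adding the 17824 probe sets without a single symbol ended the calls of 23 named genes, which were Eloc, Atf4, Ndufa4, Ndufa1, Ndufb5, Cox5a, Fdft1, Tnfrsf10b, Plac8, S100a8, Mmp9, Flt1, Eng, Twist1, Lsr, Vcam1, Fcgr3, Lama4, Timp3, Vcan, Tnfrsf12a, Sema3d and Kdm5c.

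**Figure D1:**
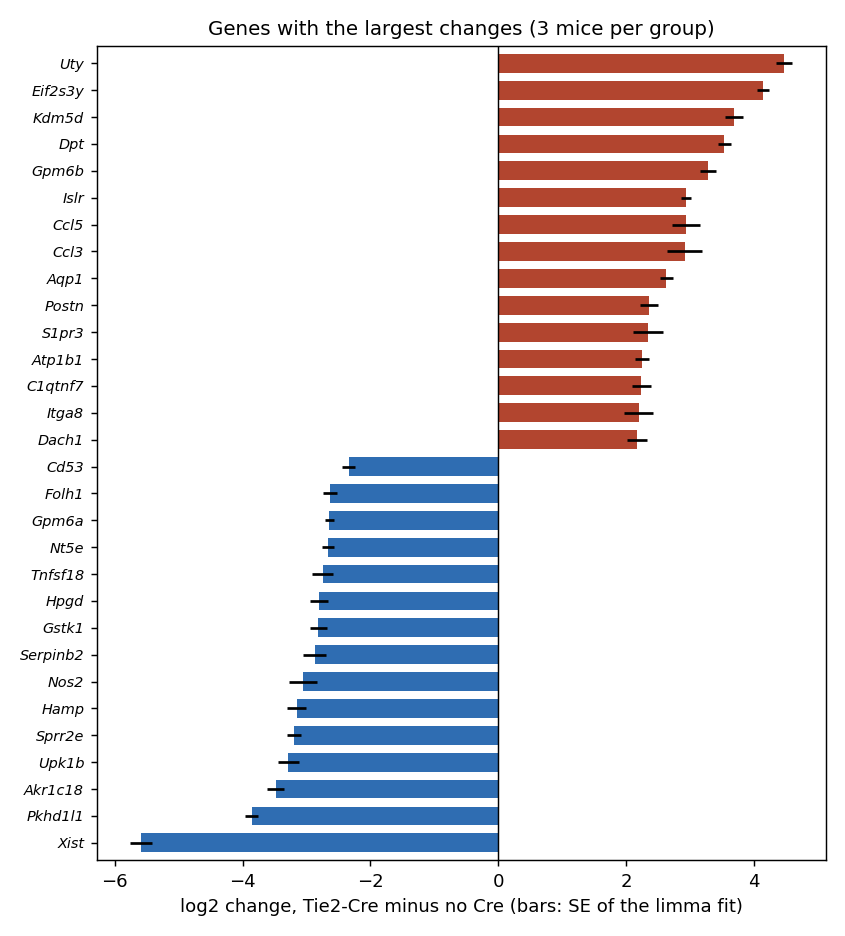
Log2 change (Tie2-Cre minus no Cre, n = 3 mice each) of the genes named by the rule among the largest rises and falls; bars give the change and lines its SE. The changes ran from -5.59 for Xist to 4.47 for Uty.

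Sex-linked genes separated the groups. Xist, the RNA that silences an X chromosome, lay at 5.36 to 6.06 log2 with Tie2-Cre and at 11.16 to 11.44 without Cre, a change of -5.59 (SE 0.17, adjusted p 2.37e-06). The Y-linked genes Uty (4.47, SE 0.13), Eif2s3y (4.14, SE 0.087) and Kdm5d (3.70, SE 0.14) were higher in all 3 Tie2-Cre mice. Of the 4 measured genes of this list, 3 were higher and 1 lower, and none of the arrays lay with the other group. This is the pattern of male cells with Tie2-Cre and of female cells without Cre. Every gene group described here was compared between the same sets of mice as Xist, so each comparison is also one between the sexes.

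Genes of the hypoxia response were lower with Tie2-Cre. Of 36 measured, 18 were lower, 1 higher and 17 did not pass the threshold; adjusted over the list alone, 23 were lower and 1 higher. Heme oxygenase Hmox1 changed by -1.40 (SE 0.087, adjusted p 7.39e-05), the adenylate kinase Ak4 by -1.60 (SE 0.16), the mitochondrial protein gene Fam162a by -1.35 (SE 0.13) and the oxidoreductase Ero1a by -0.63 (SE 0.065). Named after their values were seen, the angiogenic growth factor Vegfa changed by -0.64 (SE 0.11, adjusted p 0.00735) and the mitophagy gene Bnip3 by -1.13 (SE 0.12). The 1 higher member, also named after its values were seen, was the VEGF receptor Flt1 (1.11, SE 0.25), whose call was lost without no Cre mouse 6, 7 or 10 (adjusted p 0.0732, 0.0655 and 0.0909). The list median was -0.34 (camera adjusted p 6.15e-09), with an adjusted p of 0.125 with an estimated correlation and of 0.00331 by fry. The same arrays were low in Xist (-5.59) and higher in pericyte markers (median 0.32).

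Glycolysis genes were lower as well, with 7 of 13 lower, 0 higher and 6 not past the threshold, and 8 lower adjusted over the list alone. Examples were the glycolytic enzymes Pgam1 (-0.76, SE 0.089, adjusted p 0.00142), Pfkp (-0.52, SE 0.076), Pgk1 (-0.48, SE 0.073) and Hk2 (-0.49, SE 0.080). Over the whole list, the median was -0.36 (camera adjusted p 0.000124, and an adjusted p of 0.374 with an estimated correlation). Among 15 components of the HIF pathway, 1 was higher, 2 lower and 12 did not pass the threshold, and adjusted over the list alone 2 were higher and 5 lower. The higher one was Epas1, which encodes HIF-2 alpha (1.29, SE 0.12, adjusted p 0.00044). The oxygen sensor Egln1 (-0.31, SE 0.062) and Eloc, a subunit of the VHL ligase (-0.31, SE 0.082), were lower. The call of Egln1 was lost without no Cre mouse 7 or 10 (adjusted p 0.0575 and 0.0581), and that of Eloc without Tie2-Cre mouse 1, 3 or 4 or no Cre mouse 6 or 7 (adjusted p 0.0809 to 0.147) and with centred arrays. Egln2 (0.23, adjusted p 0.0807) and, named after its values were seen, Hif1a (-0.36, SE 0.12, adjusted p 0.0957) did not pass. Hif1a passed with the mean of its probe sets (-0.43, SE 0.093, adjusted p 0.0231, within 0.0231 to 0.888 over its alternatives) and was -0.23 without Tie2-Cre mouse 4 and -0.09 with the macrophage covariate. Egln2 passed with the dimmest genes left out (adjusted p 0.0386) and with eBayes with trend and robust (0.0347), within 0.0347 to 0.377 over its alternatives. For the list, the median was -0.12 and its mean -0.02 (camera adjusted p 0.565), and the median moved to -0.04 without Tie2-Cre mouse 1, -0.06 without Tie2-Cre mouse 4, -0.21 without Tie2-Cre mouse 3 and -0.18 without no Cre mouse 10. The glycolysis list was read in the same mice as the pericyte (median 0.32) and fibroblast markers (0.22).

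**Figure D2:**
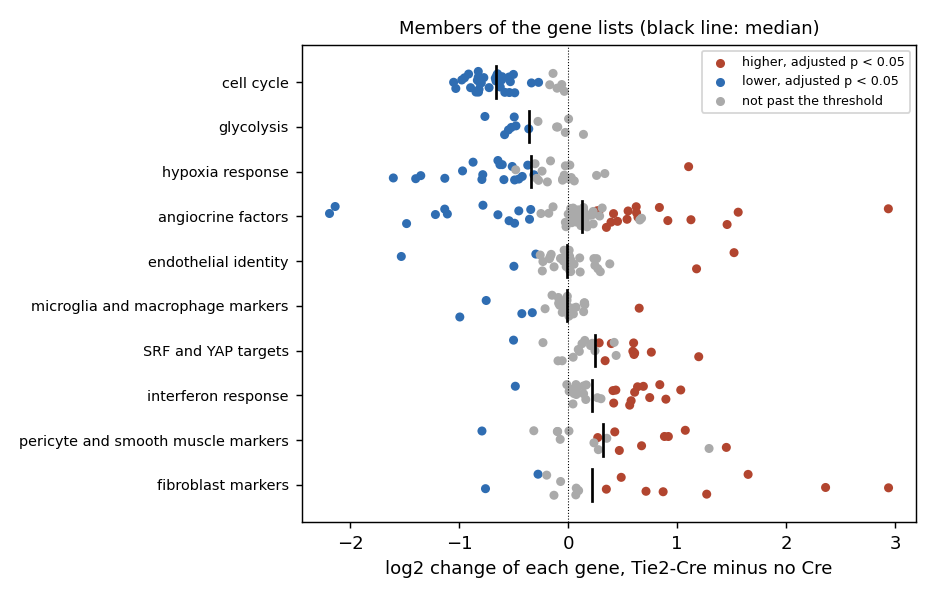
Log2 change (Tie2-Cre minus no Cre, n = 3 mice each) of every measured member of the lists shown; points are genes and the black line is the list median. The cell cycle median lay at -0.66 and the hypoxia response median at -0.34.

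Angiocrine factors, the signals endothelial cells send to their surroundings, moved both ways. Of 67 measured, 17 were higher, 13 lower and 37 did not pass the threshold; adjusted over the list alone, 23 were higher and 14 lower. Ccl5 rose by 2.94, while stem cell factor (Kitl, -2.14, SE 0.076, adjusted p 6.45e-06), the EGF receptor ligand epiregulin (Ereg, -1.48, SE 0.074) and the cytokine Il1a (-2.19, SE 0.17) were lower. Across its members, the median was 0.13 (camera adjusted p 0.0111, and an adjusted p of 0.125 with an estimated correlation). Its call was also lost by fry (adjusted p 0.0648) and with the macrophage covariate (adjusted p 0.187), within a range of 0.00273 to 0.187 over all alternatives. The median was 0.087 without Tie2-Cre mouse 3 and 0.083 without no Cre mouse 6. Of 31 angiogenesis and tip cell genes, 11 were higher, 2 lower and 18 did not pass, and 12 were higher and 3 lower adjusted over the list alone. Angiopoietin-2 (Angpt2) rose by 1.56 (SE 0.13, adjusted p 0.000351), the basement membrane protein Nid2 by 1.32 (SE 0.10) and the VEGF co-receptor Nrp1 by 0.77 (SE 0.083). The lower members were the secreted proteoglycan Esm1 (-0.78, SE 0.089) and, named after its values were seen, the laminin Lama4 (-0.75, SE 0.18). The call of Lama4 was lost without Tie2-Cre mouse 1 or no Cre mouse 6, 7 or 10 (adjusted p of at least 0.0513). The list median was 0.16 (camera adjusted p 2.40e-05, and an adjusted p of 0.125 with an estimated correlation). These 2 lists were read in the same mice as the pericyte markers (median 0.32) and Xist (-5.59).

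Cell cycle genes fell together. Of 36 measured, 31 were lower, 0 higher and 5 did not pass the threshold, with the same counts of 31 and 0 adjusted over the list alone. The mitotic kinase Cdk1 changed by -1.05 (SE 0.082, adjusted p 0.000221), thymidylate synthase (Tyms) by -0.91 (SE 0.076) and the replication helicase subunits Mcm5 and Mcm7 by -0.84 (SE 0.080) and -0.82 (SE 0.067). Over the whole list, the median was -0.66 (camera adjusted p 4.28e-22, and an adjusted p of 0.125 with an estimated correlation). Targets of p53 were lower in 7 of 20, higher in 0 and not past the threshold in 13, with 8 lower adjusted over the list alone. Perp, a desmosomal protein gene, changed by -1.94 (SE 0.20), the p53 ligase Mdm2 by -0.50 (SE 0.064) and the pro-apoptotic Pmaip1 by -0.63 (SE 0.097). For the list, the median was -0.13 (camera adjusted p 0.00422, and an adjusted p of 0.444 with an estimated correlation) and -0.21 with the macrophage covariate. The 2 lists were read in the same mice as Xist (-5.59) and the pericyte (median 0.32) and fibroblast markers (0.22).

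Of 31 genes of oxidative phosphorylation, 6 were lower, 0 higher and 25 not past the threshold, and 8 were lower adjusted over the list alone. The respiratory chain subunits Ndufa4 (-0.36, SE 0.076, adjusted p 0.0203) and Ndufa1 (-0.41, SE 0.095, adjusted p 0.0278) were examples. Both calls were lost without Tie2-Cre mouse 1 or no Cre mouse 7 or 10, and that of Ndufa1 also without Tie2-Cre mouse 4 (adjusted p 0.0572 to 0.0984 for both). Across its members, the median was -0.10 (camera adjusted p 0.00247, and an adjusted p of 0.319 with an estimated correlation) and -0.17 with the macrophage covariate. This list was read in the same mice as the pericyte (median 0.32) and fibroblast markers (0.22). Cholesterol synthesis genes were lower in 3 of 19, higher in 0 and not past in 16, and adjusted over the list alone 4 were lower and 1 higher. The lower ones were the sterol enzymes Sc5d (-0.44, SE 0.063), Msmo1 (-0.43, SE 0.071) and Fdft1 (-0.32, SE 0.067), the last of which was lost without Tie2-Cre mouse 1 or 4 or any no Cre mouse (adjusted p 0.0511 to 0.0739). This list had a median of -0.10 and did not pass by camera (adjusted p 0.0815). It passed with the added probe sets (0.0469), with the macrophage covariate (0.00628) and without Tie2-Cre mouse 3 (0.0467), within 0.00628 to 0.445 over all alternatives. Its median was -0.01 without Tie2-Cre mouse 1, -0.06 without Tie2-Cre mouse 3 or no Cre mouse 10, and -0.22 with the covariate. The unfolded protein response held 1 higher, 0 lower and 20 other members, with 0 past the threshold adjusted over the list alone (limma), and its median was -0.04 (camera adjusted p 0.488), -0.09 without Tie2-Cre mouse 3, -0.02 with the macrophage covariate and -0.0027 after another quantile normalization. Its higher member was the transcription factor Atf4 (0.31, SE 0.071, adjusted p 0.0287), a call lost without Tie2-Cre mouse 3 or 4 or any no Cre mouse (adjusted p 0.0598 to 0.0977).

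Profilin and actin regulators moved both ways, with 8 of 44 higher, 4 lower and 32 not past the threshold, and 11 higher and 5 lower adjusted over the list alone. The lower ones were the formin Diaph3 (-0.85, SE 0.083, adjusted p 0.000636), the membrane linker ezrin (Ezr, -0.45, SE 0.074), the Arp2/3 activator Wasf1 (-0.54, SE 0.098) and, named after its values were seen, Enah (-0.58, SE 0.11). Evl, which like Enah belongs to the Ena/VASP family, was higher (0.39, SE 0.074). Without no Cre mouse 7 the calls of Enah and Evl were lost (adjusted p 0.0547 and 0.0560). The list median was 0.06 (camera adjusted p 0.0436, and an adjusted p of 0.444 with an estimated correlation). Its call was kept without Tie2-Cre mouse 1 and lost when any other mouse was left out (adjusted p 0.0521 to 0.146), and also by fry (0.0648), with a minimum mean log2 of 5 (0.0538), with centred arrays (0.0509), with the mean of the probe sets (0.0908) and with the macrophage covariate (0.687), and its median was 0.095 after another quantile normalization. Targets of SRF and YAP, transcription regulators tied to actin and tension, were higher in 9 of 23, lower in 1 and not past in 13, and 11 were higher and 2 lower adjusted over the list alone. The myosin light chain Myl9 rose by 1.20 (SE 0.10, adjusted p 0.000333), the actin crosslinker Flna by 0.59 (SE 0.071) and the focal adhesion protein Tgfb1i1 by 0.61 (SE 0.082), while the focal adhesion protein zyxin (Zyx) was lower (-0.50, SE 0.085). Over the whole list, the median was 0.25 (camera adjusted p 1.02e-05, and an adjusted p of 0.374 with an estimated correlation) and 0.14 with the macrophage covariate, and the pericyte and smooth muscle markers were higher in the same arrays (median 0.32).

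Interferon response genes were higher in 12 of 28, lower in 1 and not past the threshold in 15, with 13 higher and 1 lower adjusted over the list alone. The RNA sensors Ifih1 and Ddx58 rose by 0.90 (SE 0.099, adjusted p 0.00111) and 0.57 (SE 0.083), the virus restriction factor Bst2 by 0.84 (SE 0.13) and the chemokine Cxcl9 by 0.42 (SE 0.061). The lower member, named after its values were seen, was the GTPase Irgm1 (-0.48, SE 0.088). For the list, the median was 0.22 (camera adjusted p 8.87e-07, and an adjusted p of 0.125 with an estimated correlation), and it was 0.34 with the dimmest genes left out and 0.37 with the macrophage covariate. Adhesion and inflammation genes were higher in 7 of 25, lower in 4 and not past in 14, and 8 were higher and 5 lower adjusted over the list alone. The chemokine Cxcl5 rose by 2.01 (SE 0.27) and E-selectin (Sele) by 0.88 (SE 0.15). The lower ones were the acute phase gene Saa3 (-1.03, SE 0.16), the cyclooxygenase Ptgs2 (-0.48, SE 0.074) and, named after their values were seen, Tnfaip3 (-0.73, SE 0.14) and the leukocyte adhesion molecule Vcam1 (-0.78, SE 0.17). Without no Cre mouse 7 the call of Tnfaip3 was lost (adjusted p 0.0519), and that of Vcam1 was lost without no Cre mouse 6, 7 or 10 (0.0714, 0.0641 and 0.0640). Across its members, the median was 0.12 (camera adjusted p 0.0284, and an adjusted p of 0.578 with an estimated correlation). This list deviated from its mean over all arrays by 0.20 and 0.24 in Tie2-Cre mice 1 and 3. It lay at -0.18 in Tie2-Cre mouse 4, below the no Cre mice at -0.093 to -0.079. Its call was lost by fry (0.430), with the dimmest genes left out (0.0528) and without Tie2-Cre mouse 1 (0.121), Tie2-Cre mouse 3 (0.184) or no Cre mouse 7 (0.0521), and the median was 0.26 without Tie2-Cre mouse 4 and 0.33 with the macrophage covariate. Among 19 immediate early genes, 5 were higher, 1 lower and 13 not past, and 5 were higher and 4 lower adjusted over the list alone. The higher ones were the nuclear receptors Nr4a1 (1.38, SE 0.16) and Nr4a3 (1.76, SE 0.21), the mRNA-decay factor Zfp36 (0.58, SE 0.073) and, named after their values were seen, Nr4a2 (0.80, SE 0.13) and Klf6 (0.61, SE 0.080), while Ier3 was lower (-0.94, SE 0.11). The median was 0.05 (camera adjusted p 0.214) and -0.02 without Tie2-Cre mouse 3, 0.02 without Tie2-Cre mouse 1, 0.07 without Tie2-Cre mouse 4, 0.03 without no Cre mouse 6 or 10 and 0.13 with the macrophage covariate. All of these lists were read in the same mice as the pericyte (median 0.32) and fibroblast markers (0.22) and Xist (-5.59).

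Basement membrane and matrix genes were higher in 10 of 31, lower in 5 and not past the threshold in 16, and 12 were higher and 6 lower adjusted over the list alone. Besides Nid2 (1.32), the membrane-anchored protease Mmp14 (0.56, SE 0.068), the laminin Lama5 (0.60, SE 0.078) and the proteoglycan agrin (Agrn, 0.67, SE 0.093) rose. The lower ones were the gelatinase Mmp9 (-0.44, SE 0.098) and, named after their values were seen, Lama4 (-0.75, SE 0.18), the gelatinase Mmp2 (-0.44, SE 0.083), the protease inhibitor Timp3 (-0.48, SE 0.10) and the proteoglycan versican (Vcan, -0.47, SE 0.12). Only the call of Mmp2 among these 5 was kept whichever mouse was left out. That of Timp3 was lost without Tie2-Cre mouse 1 or 3 or any no Cre mouse (adjusted p 0.0572 to 0.0669), those of Vcan and Lama4 without Tie2-Cre mouse 1 or any no Cre mouse (0.0513 to 0.109), and that of Mmp9 without Tie2-Cre mouse 1 or 3 or no Cre mouse 7 or 10 (0.0628 to 0.0891). The list median was 0.10 (camera adjusted p 0.0282, and an adjusted p of 0.358 with an estimated correlation). Its call was lost without Tie2-Cre mouse 4 (median 0.042, adjusted p 0.0617) and with the macrophage covariate (median 0.022, adjusted p 0.187). The fibroblast markers were higher in the same arrays (median 0.22).

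Markers of endothelial identity showed no common direction, with 2 of 34 higher, 3 lower and 29 not past the threshold, and the same counts of 2 and 3 adjusted over the list alone. The sialomucin Cd34 changed by -1.53 (SE 0.071, adjusted p 1.62e-05) and the transcription factor Fli1 by -0.50 (SE 0.079), while Ecscr (1.18, SE 0.12) and the adhesion receptor Adgrl4 (1.52, SE 0.21) rose. Eng, which encodes the antigen used for sorting and was named after its values were seen, changed by -0.30 (SE 0.064, adjusted p 0.0217). The call of Eng was kept without Tie2-Cre mouse 3 and lost without any other mouse (adjusted p 0.0571 to 0.0827). Over the whole list, the median was -0.0060 and its mean 0.025, with camera pointing up (adjusted p 0.838) and fry down (adjusted p 0.198). The median level of the list was 7.06 log2, at the 43.8th percentile of random lists of its size. The lack of a common change therefore does not show that endothelial identity was kept. Of 26 blood-brain barrier genes, 3 were higher, 8 lower and 15 not past, with 3 higher and 9 lower adjusted over the list alone. The forkhead factor Foxf2 (-0.73, SE 0.076), the efflux pump Abcg2 (-0.76, SE 0.087) and the monocarboxylate carrier Slc16a1 (-0.84, SE 0.12) were lower. The taurine carrier Slc6a6 (0.85, SE 0.081) was higher, as were the junction genes Cgnl1 (0.56, SE 0.095) and Lsr (0.34, SE 0.086), both named after their values were seen. The call of Lsr was kept only without no Cre mouse 6 (adjusted p 0.0509 to 0.129 without each of the others), and it was lost with array weights and with the mean of its probe sets. For the list, the median was -0.09, which passed by fry (adjusted p 0.0151) and not by camera (adjusted p 0.121, range over all alternatives 0.0151 to 0.526), and was -0.17 with the dimmest genes left out and -0.03 with the macrophage covariate.

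Pericyte and smooth muscle markers were higher in 8 of 18, lower in 1 and not past the threshold in 9, and 11 were higher and 2 lower adjusted over the list alone. The pericyte gene Rgs5 rose by 1.45 (SE 0.063, adjusted p 1.29e-05), the receptor Notch3 by 1.08 (SE 0.10) and smooth muscle actin (Acta2) by 0.47 (SE 0.082), while Ndufa4l2 was lower (-0.79, SE 0.088). Across its members, the median was 0.32 (camera adjusted p 0.000353, and an adjusted p of 0.125 with an estimated correlation). Fibroblast markers were higher in 8 of 16, lower in 2 and not past in 6, with the same counts of 8 and 2 adjusted over the list alone. Besides Islr (2.94) and Postn (2.36), the growth factor receptor Pdgfra rose by 1.65 (SE 0.13) and the surface glycoprotein Thy1 by 0.87 (SE 0.076). The lower ones, named after their values were seen, were the proteoglycan decorin (Dcn, -0.76, SE 0.10, adjusted p 0.00244) and Twist1 (-0.28, SE 0.074, adjusted p 0.0490), whose call was lost without any 1 of the 6 mice (adjusted p 0.0548 to 0.152), after another quantile normalization, with centred arrays and with array weights. The collagen genes Col1a1 (-0.07, SE 0.065) and Col3a1 (-0.20, SE 0.084), also named after their values were seen, did not pass the threshold. The list median was 0.22 (camera adjusted p 0.000353, and an adjusted p of 0.125 with an estimated correlation), and 0.35 with the dimmest genes left out.

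**Figure D3:**
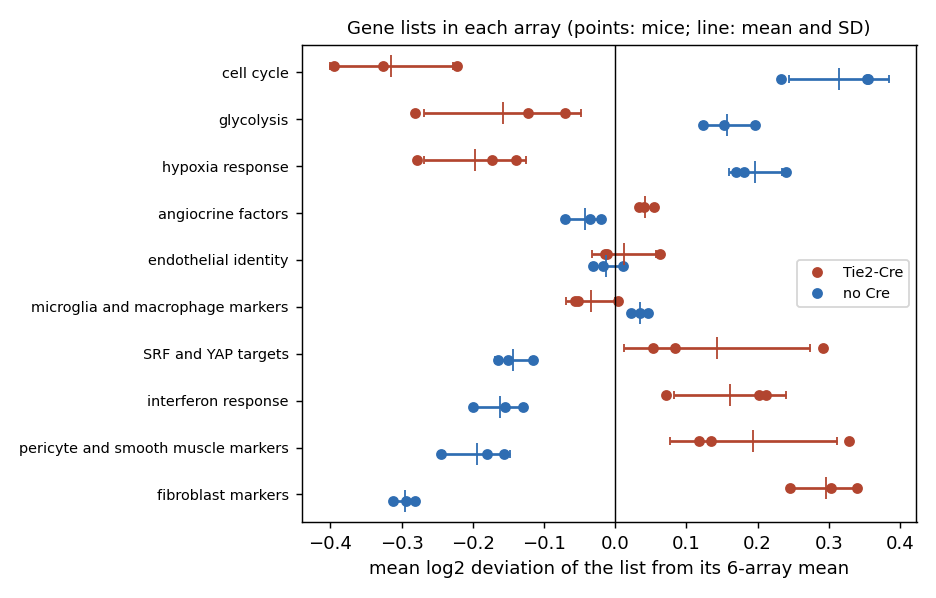
Mean deviation of 10 lists from the mean over all arrays (log2), per mouse; points are mice, and the lines give the mean and SD of each group of 3. In the cell cycle list every Tie2-Cre mouse lay below every no Cre mouse.

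Microglia and macrophage markers were higher in 1 of 27, lower in 4 and not past the threshold in 22, with the same counts of 1 and 4 adjusted over the list alone (median -0.01, camera adjusted p 0.478). The lysosomal protein gene Cd68 (-0.99, SE 0.082), lysozyme Lyz2 (-0.75, SE 0.098), the receptor Csf1r (-0.42, SE 0.068) and, named after its values were seen, the Fc receptor Fcgr3 (-0.33, SE 0.085) were lower, and the microglial gene Tmem119 was higher (0.65, SE 0.11). The call of Fcgr3 was lost without any 1 of the 6 mice (adjusted p 0.0563 to 0.137) and with centred arrays. Neutrophil and monocyte markers were lower in 4 of 17, higher in 0 and not past in 13, also adjusted over the list alone (median -0.05, camera adjusted p 0.0929). The lower ones were Ly6c2 (-0.62, SE 0.11), Plac8 (-0.53, SE 0.11), S100a8 (-0.55, SE 0.11) and Mmp9 (-0.44, SE 0.098). The calls of Plac8 and S100a8 were lost without no Cre mouse 7 or 10, that of S100a8 also without Tie2-Cre mouse 3 (adjusted p 0.0513 to 0.0605 for both). This list passed with the dimmest genes left out (0.0460) and without no Cre mouse 6 (0.0307), within 0.0307 to 0.374 over all alternatives. Its median was -0.36 with the dimmest genes left out, -0.13 without no Cre mouse 7, -0.09 without no Cre mouse 6 and -0.12 with the macrophage covariate. Of 18 T and NK cell markers 1, the chemokine Ccl5, was higher, 0 were lower and 17 not past, also adjusted over the list alone (median 0.05, camera adjusted p 0.181). Astrocyte, progenitor and glioma markers were higher in 2 of 19, the intermediate filament nestin (Nes, 0.59, SE 0.080) and the calcium-binding S100b (0.57, SE 0.11, lost without Tie2-Cre mouse 3 at an adjusted p of 0.0514), with 0 lower and 17 not past, also adjusted over the list alone (median 0.04, camera adjusted p 0.181). The neuronal tubulin Tubb3 (1.06, SE 0.073) was the 1 higher of 14 neuron markers, with 0 lower and 13 not past, also adjusted over the list alone (median 0.07, camera adjusted p 0.121). The neuron list passed with the macrophage covariate (0.0278) and without Tie2-Cre mouse 3 (0.0467), within 0.0278 to 0.444 over all alternatives. All 11 oligodendrocyte markers missed the threshold (limma, also adjusted over the list alone), among them Mbp (-0.14, SE 0.076), Cldn14 (0.13, SE 0.10), Mal (-0.16, SE 0.13) and Ugt8a (0.15, SE 0.14), with a list median of 0.03 (camera adjusted p 0.838). The 3 measured red blood cell markers Slc4a1, Epor and Klf1 did not pass either, with a median of 0.08, and were too few for a list test. Leaving out each mouse moved the medians of lists that had not passed by over 1.5 times, to 0.02 to 0.08 for T and NK cell markers, 0.01 to 0.08 for astrocyte, progenitor and glioma markers, 0.04 to 0.11 for neuron markers, -0.06 to 0.01 for macrophage markers and -0.01 to 0.04 for oligodendrocyte markers. With the macrophage covariate, these medians were 0.09, 0.12, 0.17, 0.05 and 0.10 in that order. With the dimmest genes left out, the astrocyte, progenitor and glioma median was 0.10 and the neuron median 0.11. Among random lists, macrophage markers lay at percentile 12.3 in level, T and NK cell markers at 5.6 and neutrophil and monocyte markers at 3.2. Astrocyte, progenitor and glioma markers lay at 16.8, oligodendrocyte markers at 22.1 and neuron markers at 29.1. The lack of a common change in such dim lists therefore does not show that the share of these cells was alike.

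Of the 26 lists tested by camera with the preset correlation, 14 passed the threshold, 9 up and 5 down. With an estimated correlation 0 passed at an adjusted p under 0.05, where the smallest was 0.125, 7 had an unadjusted p under 0.05, and fry called 12. Only 3 mice per group and the full overlap of genotype with the sex-linked genes limit what these comparisons can separate.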

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

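Chosen only after the result was seen were the test of arrays of both sexes in a group, the tests on fibroblast and pericyte markers, the test of slower growth and the counts over other splits of the arrays.

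Sex-linked genes, which were tested with all other genes, stood apart between the groups. Xist was lower with Tie2-Cre (-5.59 log2), and the Y-linked genes Eif2s3y (4.14), Uty (4.47) and Kdm5d (3.70) were higher. That the Tie2-Cre mice were male and the no Cre mice female was tested on X-linked genes known to escape inactivation. Of these, Kdm5c (-0.31, SE 0.067), Kdm6a (-0.56, SE 0.064) and Ddx3x (-0.47, SE 0.082) were measured. Their median change was -0.47, as that explanation predicts. Xist and the Y-linked genes, without overlap between the groups in any array, already mark the Tie2-Cre cells as male and the no Cre cells as female. The call of Kdm5c was lost without Tie2-Cre mouse 1 or 4 or no Cre mouse 6 or 7 (adjusted p 0.0558 to 0.0830). Whether the sex difference accounts for the genes past the threshold cannot be told apart from the genotype, since 0 of the groups held arrays of both sexes, and the genotype, which is the biological difference the design names, stays untested against it.

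Fibroblast and pericyte markers were higher with Tie2-Cre in cells that had been sorted with an antibody against endoglin, a sort that should remove most other cells, although pericytes and fibroblasts can also carry endoglin. A larger share of fibroblasts of one profile would raise all their abundant transcripts. Of the fibroblast markers past the threshold, 8 were higher and 2 lower. The lower ones were Dcn (-0.76, SE 0.10), at a mean of 12.45 log2 with Tie2-Cre, and, less securely, Twist1 (-0.28, SE 0.074). Col1a1 (-0.07, SE 0.065) did not rise beside Islr (2.94). These values were known before the bound was set, so the count could not have spoken for a larger share, and that explanation stays open. A larger share of pericytes or smooth muscle cells stays open, since 72.2% of the pericyte markers (13 of 18) lay above 0. That share lies between the bounds set for and against it, with Acta2 at 13.77 and 13.30 log2. As the lists were fixed, 0 of the genes of either list stood in another list, which does not make them independent of the other lists. A loss of endothelial cells from the Tie2-Cre preparations would raise the markers of all other cells alike. Of the fibroblast and pericyte markers past the threshold, 8 of each list were higher. Lower were 3, Dcn, Twist1 and Ndufa4l2 (-0.79, SE 0.088), beside Islr. This count too was known before its bound was set, so such a loss stays open. The endothelial identity list, at a median level of 7.06 log2, had a median change of -0.0060. A change of state within the sorted cells by genotype or sex may equally give such values and was not tested.

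Hypoxia and glycolysis genes were lower with Tie2-Cre. Scaling between the arrays was tested by another quantile normalization and by centring. The hypoxia median nearer 0 of the 2 was -0.33, beyond the bound set in advance. The deposited values had already been quantile normalized, with array medians of 6.64 to 6.69 log2, so these steps could move the median little. They argue against a scale difference left between the deposited arrays and cannot test the authors' own normalization. A slower growth state of the Tie2-Cre cells stays open: the cell cycle median was -0.66, but this value was known before it was set as the test, so it could not have spoken against slower growth. The genotype and the sex of the mice stay open for both patterns.

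Of the 17824 probe sets without a single symbol, 127 passed the threshold when tested alone by limma, 58 higher and 69 lower, and 30 of them had several symbols and 97 were not listed.

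The 6 arrays make 10 splits into 3 and 3, which are too few for a share under 0.05. For the genes past the threshold, 1 of the 10 splits gave as many as the real 2652, namely the real one, and the highest of the others gave 0 by limma, with 539 to 722 genes at an unadjusted p under 0.05 against 5524. For the gene lists, 1 of the 10 splits gave as many as the real 14, and the highest of the others gave 9. Each other split sets arrays of both real groups on both sides, so a difference between the groups widens the spread within its sides. Gene counts of the other splits are thereby lowered and do not measure what chance alone gives.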

How the results depend on the processing

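None of the alternatives was chosen only after the result was seen, although 38 of the 168 genes recomputed were. No paired analysis was possible because the mouse numbers differ between the groups. The direction of Pfn1 (0.023 to 0.048 without each mouse), of the hypoxia list (-0.39 to -0.30) and of the angiocrine list (0.083 to 0.16) was kept whichever mouse was left out, and 12 to 14 lists then passed. Leaving out 1 mouse gave 634 to 903 higher and 910 to 1253 lower genes, where fewer arrays widen the spread allowed for: the higher count moved over 1.5 times without no Cre mouse 6 (667), 7 (676) or 10 (634), and the lower count without Tie2-Cre mouse 1 (1046) or no Cre mouse 6 (1022), 7 (910) or 10 (1026). Of the 147 named genes past the threshold, 12 to 27 were then lost. With the macrophage list mean as a covariate, 82 genes were higher and 152 lower (225 of the 2652 shared), 97 named genes were lost (their changes stayed at a median ratio of 1.01 while the SE grew to 2.00 times), and the angiocrine median was 0.15 (adjusted p 0.187). That covariate parted the groups by itself (6.61 to 6.67 with Tie2-Cre, 6.69 to 6.72 without), so it takes part of the contrast. Its list was dim, at percentile 12.3 of random lists, so its mean need not measure a share of macrophages. An unadjusted p under 0.05 with at least 1.5-fold gave 424 higher and 551 lower genes (944 shared). Other settings gave 849 to 1403 higher and 1193 to 2121 lower genes and 13 to 15 lists, and adding probe sets lost 23 named genes. Camera with an estimated correlation called 0 lists (7 at an unadjusted p under 0.05, 12 by fry), with the hypoxia median of -0.34 and the angiocrine median of 0.13 both at an adjusted p of 0.125. By fry the angiocrine median of 0.13 was at 0.0648. Over all alternatives the adjusted p ran from 2.74e-10 to 0.125 for hypoxia and from 0.00273 to 0.187 for angiocrine factors. Signs turned only in results that had not passed. The oligodendrocyte median was -0.0013 with a minimum mean log2 of 5, -0.042 without the dimmest genes and -0.0094 to 0.045 without each mouse (below 0 without Tie2-Cre mouse 1 and no Cre mouse 7). The endothelial median was 0.0063 with centred arrays. The macrophage median was 0.0018 with centred arrays, 0.052 with its own mean as covariate and -0.063 to 0.0051 without each mouse (above 0 without Tie2-Cre mouse 4). The immediate early median was -0.021 to 0.074 (below 0 without Tie2-Cre mouse 3), Ugt8a -0.0062 to 0.28 (below 0 without Tie2-Cre mouse 1), and Mal 0.21 with the covariate. The cause was not tested for any of these beyond what is said. The background of the arrays limits the folds of dim genes, and no detection call was used.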

Other observations

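The gene families here were chosen only after their members' values had been seen, so a test of a family would run on genes chosen for the pattern, and counts and medians are given without one. Of 20 families looked at, 5 are described, and the other 15 held 0 to 7 higher and 0 to 6 lower members each, where 1061 of all 22180 genes were higher and 1591 lower. Ligands and receptors of the TNF superfamily were lower with Tie2-Cre in 8 of 29 and higher in 1 (median -0.08). Tnfsf18 changed by -2.75 (SE 0.16) and, named after their values were seen, the receptor gene Tnfrsf26 by -2.32 (SE 0.062), Tnfsf15 by -2.16 (SE 0.11) and the T cell co-stimulatory receptor Tnfrsf9 by -1.12 (SE 0.084). The 1 higher member, also named after its values were seen, was the TWEAK receptor Tnfrsf12a (0.39, SE 0.097), whose call was kept only without Tie2-Cre mouse 1 (adjusted p 0.0600 to 0.122 without each of the others). Chemokines were higher in 8 of 34 and lower in 0 by limma (median 0.11). Besides Ccl5 (2.94), Ccl3 (2.92) and Cxcl5 (2.01), the leukocyte attractants Cx3cl1 (1.35, SE 0.14) and Ccl9 (1.21, SE 0.20) rose, both named after their values were seen. Class 3 semaphorins, secreted guidance signals, moved both ways among 7 measured, and those given here were named after their values were seen. Sema3c (-2.01, SE 0.093), Sema3e (-1.74, SE 0.24) and Sema3d (-0.53, SE 0.12) were lower, and Sema3b (1.31, SE 0.093) and Sema3f (0.92, SE 0.065) higher. The call of Sema3d was kept only without Tie2-Cre mouse 4 (adjusted p 0.0577 to 0.0872 without each of the others).

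Cytosolic ribosomal protein genes were lower in 11 of 53 and higher in 0 by limma (median -0.20), with Rps18 (-0.55, SE 0.068) and Rpl37a (-0.54, SE 0.073) as examples named after their values were seen. The probe sets of Rps18 disagreed, and with their mean its change was -0.08 (SE 0.069, adjusted p 0.544, against 0.000397 to 0.0912 over its other alternatives). Of the NR4A and other nuclear receptors, 5 of 21 were higher and 1 lower (median 0.07), and 3 of the 5 were the NR4A genes already described. The medians of these families kept their sign under another quantile normalization and under centring. These counts compare the same mice as Xist (-5.59) and the pericyte markers (median 0.32).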
